A study of Homo sapiens with 30 samples.

How the data were processed

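Total RNA of T-HESC cells was measured 48 hours after transfection with 50 nM of control siRNA or of siRNA labelled BRCA, C11orf9, ETV6 or FLI1. Libraries were stranded and depleted of ribosomal RNA, with 3 biological replicates per group, and each of the 15 libraries was sequenced in 2 runs of single-end reads of 50 bases. Per the labels, a knockdown of over 70% by qPCR was required. The authors' notes name the hg38 genome, HISAT2 2.1.0, StringTie 1.3.6, edgeR, limma and DESeq2 2.11.40.6, without their options or the annotation release.

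The authors deposited 1 table of DESeq2 output per knockdown, with 100454 rows named by Ensembl transcript. The signal in the base mean column is, per the file headers, the mean over the libraries of a table of the transcript counts after division by the size factors of the authors. The log2 fold change and its standard error were made by the authors with DESeq2, on the log2 scale, and are moderated: transcripts with 1 count in 1 library had absolute values of 0.46 to 0.53. The Wald score in the deposited tables is the log2 fold change divided by its standard error. The p-value and the adjusted p-value, with Benjamini-Hochberg correction after a filter on low base means, were computed by the authors. The headers do not give the direction of the fold change. It was read from the lowest base means, which stand for 1 count in a single library: they formed 6 levels per table, 3 with negative and 3 with positive fold changes, and the relative depths of the negative side were alike in all 4 tables, so that side is the shared control. Base means summed to between 6.51e+06 and 6.57e+06 per table. Between 1927 and 1989 transcripts per table had counts but no p-value, and the filter left 22223 to 23743 transcripts with an adjusted p. The tables hold 0 columns of values for single samples.

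Calls were the authors' own, at an adjusted p under 0.05. Transcript identifiers were matched to GENCODE release 29, which named 83066 of them (82.7%) and over 98.2% of the base mean sum in each table. From each base mean and fold change the mean normalised counts of the control and knockdown groups were derived. As the fold changes are moderated, changes of noisy transcripts are drawn towards 0 in these means and in the values built on them. A group mean under 1 (a floor of 3 counts over the 3 libraries) was set to 1, and the fold given as a lower bound. The main tests, the genes to be named, the gene lists and the alternatives were fixed before the data were examined. The rule for named genes took, for each knockdown, the siRNA target, the 10 transcripts with the largest rise and the 10 with the largest fall among called protein-coding transcripts with a base mean of at least 50, 1 per gene, and up to 4 called members of each list by size of change. Between knockdowns it took the 10 genes called in the same direction in the most tables. Some of the transcripts so taken are summarised in the text by count.

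Gene lists (26) were tested with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, on the deposited Wald scores, with 1 transcript per gene, that of highest base mean, a base mean of at least 10, and at least 3 measured members. The preset correlation between genes was 0.01. A correlation could not be estimated without values per library, so a preset correlation of 0.05 was used beside it. Benjamini-Hochberg correction covered the 100 tests of all lists and knockdowns. Members were also counted when adjusted over the list alone.

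After the tables had been seen, transcripts were summed per gene in each group (base mean of at least 10), and a Wald test was made on the log2 ratio of the sums. Its standard error came from those of the transcripts, taken as independent. This error is too large where transcripts of a gene trade reads, so a total that did not pass may still have changed. A gene with 1 listed transcript kept its deposited change and error. For a transcript with a group mean under 5 the dispersion was the larger of the value its own standard error implies and the median of transcripts of like mean. This rule replaced an earlier one, the median alone, after a test on simulated data in which the earlier rule called too many unchanged genes, and at a time when the counts of called genes had been seen. Tested on simulated data with 200 changed genes per table, the reported rule found 27 to 35 of 50 genes that fell by 2 on the log2 scale and 5 to 13 of 50 that fell by 1. It called 4 to 11 of the 11393 to 11552 unchanged genes and 0 to 1 of 100 genes with exchanged transcripts, while the transcript test called 159 to 172 of 200 such transcripts. A list shifted by 1 in its score was found in 48 to 50 of 50 simulated draws. Scores were independent between genes in these draws, so they say nothing on the correlation that the presets stand for. The simulated tables used fold changes without moderation and the dispersions they were drawn with. Their rates may thus be better than those in the data.

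Knockdowns were compared in pairs by the difference of their log2 fold changes over the root of the summed squared standard errors, with Benjamini-Hochberg correction within each pair. As the controls are shared, this error is too large. Gene lists were compared between knockdowns with cameraPR on such differences of gene totals, corrected over 150 tests. Overlaps of calls were set beside 20 simulated sets per pair with shared controls and no change in either knockdown. In each set the transcripts with the largest absolute scores were taken as called, as many as in the data. In those sets transcripts were drawn independently, which overstates the spread of gene totals. Alternatives were a threshold of 0.01, a minimum change of 1.5-fold, a base mean of at least 50, no filter on base means, centring on the median of transcripts with a base mean of at least 100, a t distribution with 4 degrees of freedom, the other preset correlation, ranks, and 10000 random lists matched on base mean. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Leaving out single libraries, a replicate term and other splits of the libraries were not run, since they need values per library.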

Results

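RNA was sequenced from T-HESC, a line of human endometrial stromal fibroblasts immortalised with telomerase. The cells had been transfected with siRNA at 50 nM for 48 hours. The labels give 5 groups: a control siRNA (a fluorescent non-targeting oligonucleotide, labelled Ctrl9) and siRNAs labelled BRCA, C11orf9, ETV6 and FLI1. C11orf9 is an older symbol of MYRF, and the label BRCA does not say whether BRCA1 or BRCA2 was meant. Each group had 3 biological replicates, and each of the 15 libraries was sequenced in 2 runs, which makes 30 samples. The series concerns genes that gained expression in the endometrium of placental mammals, and each comparison asked which transcripts changed when 1 such regulator was depleted. The authors' deposited tables, 1 per knockdown, list 100454 Ensembl transcripts with a mean normalised count, a log2 fold change, its standard error and p-values. The tables give no values per library. The mean normalised counts of a table summed to between 6.51e+06 and 6.57e+06, and between 33446 and 34161 transcripts had a count above 0. The lowest counts showed 6 libraries behind each table, 3 per group, with size factors between 0.921 and 1.10, so depth differed little between libraries. In all 4 tables the relative depths of the control libraries were alike (0.86 to 0.87, 0.96 to 0.97 and 1), and positive fold changes stood for higher levels after knockdown. The smallest change that can be seen is set by this depth and by 3 libraries per group.

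BRCA1 and FLI1 fell in the knockdowns named for them. In the authors' deposited table BRCA1 (chromosome 17, 43044295 to 43125483 on the minus strand of hg38), a DNA repair gene, stood at -2.18 on the log2 scale after BRCA siRNA, a reduction of 77.9% (95% interval -2.84 to -1.52, adjusted p = 5.22e-08). BRCA2 (chromosome 13, 32315474 to 32400266) stood at -0.20 in the same table by the authors' test (-0.92 to 0.52, adjusted p = 1.00). FLI1 (chromosome 11, 128693916 to 128813266), an ETS-family transcription factor, stood at -1.94 after FLI1 siRNA in the authors' deposited table, a reduction of 74.0% (-2.63 to -1.26, adjusted p = 5.12e-06). ETV6 (chromosome 12, 11649854 to 11895402), an ETS-family repressor, stood at -1.90 after ETV6 siRNA, a reduction of 73.3%, with an interval of -3.53 to -0.28 and an adjusted p of 0.480 by the authors' test, so this value did not pass the threshold. MYRF (chromosome 11, 61752649 to 61788518), a membrane-bound transcription factor, had a mean normalised count of only 5.38 in the authors' table for C11orf9 siRNA. It stood at -0.60 there (-2.95 to 1.75), and a reduction was not detectable at this depth. The labels state that a knockdown of over 70% by qPCR was required before sequencing. Outside their own knockdowns, FLI1 stood at -0.84 after BRCA siRNA (adjusted p = 0.169 by the authors' test). ETV6 stood at -1.27 after C11orf9 siRNA (adjusted p = 0.891) and at -1.12 after FLI1 siRNA (adjusted p = 0.441). BRCA1 stood at -0.73 after FLI1 siRNA (adjusted p = 0.298 by the same test). MYRF, at a mean normalised count of 3.74, stood at -1.97 after BRCA siRNA (-5.60 to 1.65, adjusted p = 0.931).

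**Figure D1:**
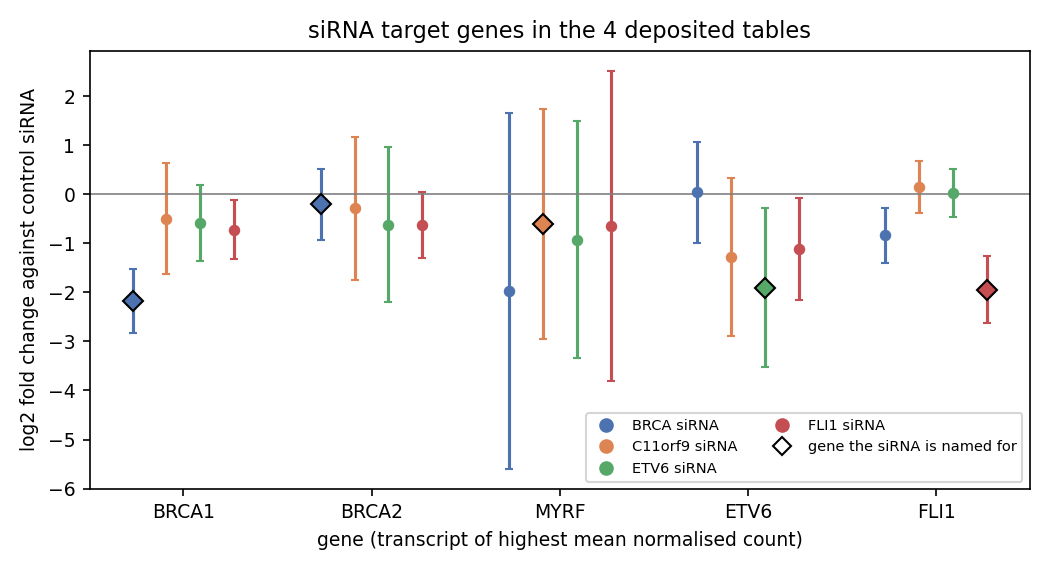
Log2 fold change against control siRNA (vertical axis) of the transcript of highest mean normalised count of each siRNA target gene (horizontal axis) in the 4 deposited tables. Colours stand for the siRNA, diamonds mark the gene an siRNA is named for, and bars span the 95% interval of the authors' standard error. BRCA1 after BRCA siRNA (-2.18) and FLI1 after FLI1 siRNA (-1.94) lie well below 0, while the bars of MYRF cross 0 in all 4 tables.

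Most large changes were of single transcripts in genes whose total moved by less than 1.5-fold. At the authors' adjusted p under 0.05, 262 transcripts changed after BRCA siRNA (50.4% of them higher), 233 after C11orf9 siRNA (48.9%), 313 after ETV6 siRNA (54.0%) and 623 after FLI1 siRNA (49.1%). In genes with several listed transcripts, 741 calls over the 4 tables had an absolute log2 fold change of 3 or more, and in 80.4% of them the summed counts of the gene moved by less than 1.5-fold in that direction or moved the other way. In 75.2% they moved by less than 1.5-fold either way. When transcripts were summed per gene, 45 genes passed the same threshold after BRCA siRNA (21 higher, 24 lower) and 23 after C11orf9 siRNA (14 and 9). After ETV6 siRNA 40 passed (20 and 20), and after FLI1 siRNA 285 (49.8% of them higher). Of these genes 30, 17, 25 and 194 had only 1 listed transcript, whose deposited change was kept, so nothing was summed for them. These gene totals were computed only after the tables had been seen, and the genes named below by their totals were chosen after their values were seen. With a t distribution of 4 degrees of freedom in place of the normal one in the DESeq2 Wald test, 0 transcripts passed in any table, although 514, 419, 572 and 924 had an unadjusted p under 0.05. All calls of single transcripts below therefore rest on the normal reference of the authors' test, whose spread is pooled across transcripts. Gene totals were tested against the normal reference too. Neither gene totals nor list tests were run with this t distribution.

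**Figure D2:**
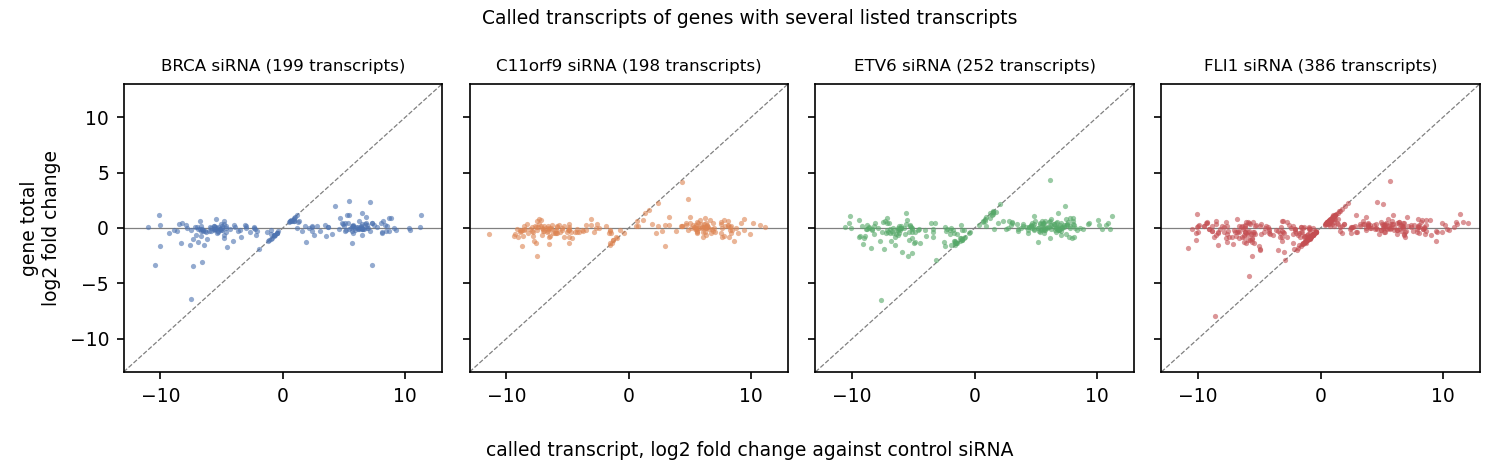
Log2 fold change of each called transcript (horizontal axis) against the log2 fold change of the summed counts of its gene (vertical axis), for genes with several listed transcripts, in the 4 knockdowns. Each point is 1 transcript and the dashed line marks equal change. Of the calls with a log2 change of 3 or more, 75.2% lie in genes whose total moved by less than 1.5-fold either way.

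After BRCA siRNA, genes of DNA replication and histone genes were lower as groups, and p53 target genes were higher as a group. Among gene totals, MCM3 and MCM6, subunits of the replicative helicase, fell by 0.89 ± 0.17 and 0.75 ± 0.13 on the log2 scale (SE). HDAC1, a histone deacetylase, fell by 1.35 ± 0.20, LDHA, the lactate dehydrogenase of glycolysis, fell by 0.97 ± 0.11, and CD44, a hyaluronan receptor, fell by 0.68 ± 0.07. The LDHA total was also on the lower side after C11orf9 (-1.12 ± 0.51), ETV6 (-1.60 ± 0.76) and FLI1 siRNA (-0.98 ± 0.26). Of these, only the value after FLI1 siRNA passed by the Wald test of gene totals (adjusted p = 0.0116). CDK6, a kinase of the cell cycle, rose by 1.18 ± 0.25, ADAMTS5, a protease of aggrecan, rose by 0.96 ± 0.22, and RHOBTB1 rose by 0.83 ± 0.09. Of 41 measured genes of DNA replication, 38 were lower, with a median log2 fold change of -0.54 (cameraPR adjusted p = 9.58e-10). MCM3, MCM6 and MCM4 passed on their own, 3 members, and 5 passed when adjusted over the list alone. By gene totals 2 members passed, and MCM4 did not (-0.60 ± 0.21, adjusted p = 0.284). Of 45 replication-dependent histone genes 43 were lower, with a median of -0.44 (adjusted p = 4.89e-12). H1-3 passed on its own, at -0.61 ± 0.18 (SE) in the authors' table, and 4 members passed when adjusted over the list alone. By the Wald test of gene totals 0 histone genes passed, with H1-3 at an adjusted p of 0.101. H1-3 has 1 listed transcript, so its value is the same there and only the set of corrected tests differs. Of 30 p53 target genes 28 were higher, with a median of 0.36 (adjusted p = 2.04e-06). By the authors' DESeq2 test 0 of them passed on their own and 0 passed when adjusted over the list alone, with CDKN1A, a cell cycle inhibitor, at 0.81 ± 0.31 (adjusted p = 0.377). Immediate early and AP-1 genes (median -0.32, 23 of 29 lower, adjusted p = 0.0235) and genes of hypoxia and glycolysis (median -0.18, 19 of 28 lower, adjusted p = 0.0417) passed only at the lower preset correlation. Their adjusted p was 0.242 and 0.282 with a preset correlation of 0.05. By the authors' DESeq2 test 0 members of the first list passed (0 when adjusted over the list alone), and of the second only LDHA did (1 member either way). Among single transcripts, 1 of TRIM2, a ubiquitin ligase, averaged 864 normalised counts after knockdown and was below the floor of 1 in control, at least 864-fold higher, while the total of TRIM2 was at 1.17 ± 0.66 (adjusted p = 1.00). A transcript of SOCS5 was at least 795-fold higher and a transcript of FUS at least 199-fold lower in the same way, with gene totals at 0.11 ± 0.64 and -1.35 ± 1.03 (adjusted p = 1.00 each). Over the 4 tables the totals of TRIM2 lay between 0.82 and 1.23 and those of FUS between -1.83 and -1.35. A stable total is thus not shown for TRIM2 or FUS.

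After C11orf9 siRNA, fewer genes passed, and p53 target genes were again higher as a group. Some errors were larger here: the MCM6 total was at -0.79 ± 0.82, against -0.75 ± 0.13 (SE) after BRCA siRNA. In simulated data the gene-total test found 5 of 50 genes that fell by 1 (log2), against 12 of 50 for BRCA. Fewer calls therefore do not show a weaker response. YWHAZ, a 14-3-3 adaptor, rose by 1.59 ± 0.12 on the log2 scale (SE, gene total), TXNIP, an inhibitor of thioredoxin and glucose uptake, by 1.37 ± 0.25, and its relative ARRDC4 by 1.01 ± 0.18. The YWHAZ total was of like size after BRCA (1.37 ± 0.59), ETV6 (1.16 ± 0.52) and FLI1 siRNA (1.75 ± 0.11). By the Wald test of gene totals it passed after FLI1 but not after BRCA or ETV6 siRNA (adjusted p = 0.816 and 0.640). As the control libraries are shared, a rise of YWHAZ particular to C11orf9 siRNA is not shown. LMNB1, which encodes lamin B1, fell by 1.53 ± 0.30, PLAT, the tissue plasminogen activator, fell by 1.51 ± 0.31, and ME1, the cytosolic malic enzyme, fell by 0.78 ± 0.18. Of 31 measured p53 target genes 27 were higher, with a median of 0.33 (adjusted p = 9.93e-06). TRIAP1, an inhibitor of apoptosis, passed on its own at 0.74 ± 0.19 (SE) in the authors' table, and 1 member passed when adjusted over the list alone. Immediate early and AP-1 genes were lower (median -0.48, 26 of 29 lower, adjusted p = 0.00405), with an adjusted p of 0.0831 at a preset correlation of 0.05. Fibrillar collagen and matrix genes were lower too (median -0.43, 36 of 42 lower, adjusted p = 0.0150), with an adjusted p of 0.242 at that correlation. No member of these last 2 lists passed on its own in the authors' DESeq2 table (0 members, and 0 when adjusted over the list alone). DNA replication genes (median -0.43, 31 of 40 lower) did not pass by cameraPR (adjusted p = 0.0579). Nor did histone genes (median -0.36, 43 of 46 lower, adjusted p = 0.0670). ADAMTS5 rose by 1.29 ± 0.35 in the authors' table (adjusted p = 0.0276 by their test). It has 1 listed transcript, so its total is that same value. Corrected over gene totals instead, it did not pass (adjusted p = 0.0999 by the Wald test). Among single transcripts, 1 of PCYT1A, a gene of phosphatidylcholine synthesis, was at least 929-fold lower, and 1 of SOCS5 at least 800-fold higher, while their gene totals were at -0.55 ± 0.71 and 0.10 ± 0.58 (adjusted p = 1.00 each). A transcript of RANGAP1, the activator of the Ran GTPase, stood at -5.42 ± 0.38 in the authors' table with its gene total at -0.01 ± 0.76 (adjusted p = 1.00).

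After ETV6 siRNA, histone, DNA replication and immediate early genes were lower as groups, and p53 target genes were higher. STRA6, a retinol transporter, fell by 2.88 ± 0.58 on the log2 scale (SE, gene total), PLAT by 1.43 ± 0.34, TMEM158 fell by 1.15 ± 0.22, BCAT1, an enzyme of branched-chain amino acid breakdown, fell by 1.01 ± 0.20, and SRD5A1, a steroid reductase, fell by 0.94 ± 0.16. C21orf91 rose by 2.86 ± 0.58, ADAMTS5 by 1.57 ± 0.23, the ephrin receptor EPHA4 by 1.38 ± 0.27, TXNIP by 1.32 ± 0.24 and TNRC6A, a protein of microRNA silencing, by 0.86 ± 0.13. The C21orf91 total was also on the higher side after BRCA (2.26 ± 0.98) and C11orf9 siRNA (2.41 ± 0.80). It did not pass there by the Wald test of gene totals (adjusted p = 0.835 and 0.427). Of 46 histone genes 44 were lower (median -0.82, adjusted p = 1.29e-07), and of 42 DNA replication genes 39 were lower (median -0.70, adjusted p = 8.64e-05). Of 27 immediate early and AP-1 genes 25 were lower (median -0.66, adjusted p = 6.20e-04), and of 31 p53 target genes 27 were higher (median 0.36, adjusted p = 6.98e-05). By the authors' DESeq2 test 0 members of these 4 lists passed on their own. When adjusted over the list alone, 1 member passed, the p53 target TRIAP1 at 0.88 ± 0.27. Contractile and SRF target genes (median -0.40, 17 of 20 lower, adjusted p = 0.00443), fibrillar collagen and matrix genes (median -0.43, 34 of 44 lower, adjusted p = 0.0174) and mitotic genes (median -0.49, 39 of 41 lower, adjusted p = 0.0297) were lower as well, with 0 members past the authors' threshold and 0 when adjusted over the list alone. These 3 calls were lost with a preset correlation of 0.05, at an adjusted p of 0.0595, 0.265 and 0.291. Among single transcripts, 1 of LIMK1, a kinase of actin turnover, was at least 277-fold lower and 1 of PDHX, a part of pyruvate dehydrogenase, at least 367-fold higher, with gene totals at -1.45 ± 1.53 and 0.68 ± 0.75 (adjusted p = 0.994 and 1.00). The LDLR transcript, for the LDL receptor, stood at -4.43 ± 1.05 and the LDHA transcript at -2.41 ± 0.67 in the authors' table, with gene totals of LDLR at -1.37 ± 1.05 (adjusted p = 0.893) and of LDHA at -1.60 ± 0.76 (adjusted p = 0.685).

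FLI1 siRNA gave the largest number of changes, with genes of DNA replication and mitosis lower. Gene totals of MKI67, a marker of cycling cells, fell by 1.28 ± 0.33 on the log2 scale (SE), of PLK1, a mitotic kinase, by 2.29 ± 0.68, of CDT1, a factor of replication licensing, by 1.84 ± 0.43, and of MYC by 1.11 ± 0.31. 3 receptors fell, GRPR, for gastrin-releasing peptide, by 3.50 ± 0.53, KIT, for stem cell factor, by 1.92 ± 0.29, and OXTR, for oxytocin, by 1.02 ± 0.24. IGFBP5, an insulin-like growth factor binding protein, fell by 2.78 ± 0.77. C21orf91 rose by 3.22 ± 0.31, the surface glycoprotein CD24 by 3.15 ± 0.53, the prostaglandin E receptor PTGER2 by 2.02 ± 0.43, the protease-activated receptor F2RL1 by 1.79 ± 0.31, YWHAZ by 1.75 ± 0.11, and SPARC, an abundant matrix protein, by 0.74 ± 0.17. Totals of C21orf91 and YWHAZ were on the higher side in every other table too, as given above, against the same control libraries. The IGFBP5 total was at -1.05, -1.24 and -1.76 after BRCA, C11orf9 and ETV6 siRNA, and that of PLK1 at -0.77, -0.68 and -1.07. Totals of MKI67 and MYC were on the lower side there too, and none of these passed. A fall particular to FLI1 siRNA is not shown for these genes. Totals of GRPR, KIT, OXTR, PTGER2, F2RL1 and SPARC took both signs in the other tables. Of 41 DNA replication genes 39 were lower, with a median of -0.99 (adjusted p = 7.15e-13). By the authors' test 10 passed on their own and 17 when adjusted over the list alone, with GINS1 at -1.28 ± 0.22, CLSPN at -1.52 ± 0.44 and MCM6 at -1.19 ± 0.34. Of 39 mitotic genes 35 were lower (median -0.46, adjusted p = 1.63e-06), and 6 passed on their own, as many as when adjusted over the list alone, among them KIF4A at -1.30 ± 0.39 in the authors' table. The largest changes in both lists were of single transcripts. The RRM2 transcript, for a subunit of ribonucleotide reductase, was at least 742-fold lower and that of CDC20, an activator of the anaphase-promoting complex, at least 384-fold lower. The gene totals of RRM2 and CDC20 were at -1.82 ± 1.16 and -1.13 ± 1.11 and did not pass (adjusted p = 0.661 and 0.909). By gene totals 8 replication genes and 4 mitotic genes passed. Of 46 histone genes 42 were lower (median -0.40, adjusted p = 1.05e-05), H3C12 passed on its own at -0.74 ± 0.18 in the authors' table, and 7 passed when adjusted over the list alone. Of 29 p53 target genes 22 were higher (median 0.29, adjusted p = 0.0373), with an adjusted p of 0.280 at a preset correlation of 0.05. In the authors' table BBC3, an inducer of apoptosis, rose by 0.86 ± 0.24 and TRIAP1 by 0.58 ± 0.17, and the same number, 2, passed when adjusted over the list alone.

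Single members of other lists also passed after FLI1 siRNA in the authors' table. Of 31 genes of decidual and endometrial stroma, PDGFRA rose by 0.46 ± 0.10, while DKK1, an inhibitor of Wnt signalling, fell by 0.93 ± 0.27, IGFBP5 fell, and a transcript of STAT3 fell by 3.07 ± 0.70. Adjusted over the list alone, 2 rose and 4 fell. The total of STAT3 was at -0.37 ± 0.70 (adjusted p = 1.00), and the list as a whole did not pass in any knockdown (smallest adjusted p 0.652, after BRCA siRNA). In the authors' table DICER1, of microRNA processing, rose by 1.08 ± 0.24, DDIT4, a stress-induced inhibitor of growth signalling, by 1.18 ± 0.34, and the glucose transporter SLC2A3 by 0.49 ± 0.12. In the same table of the authors SERPINB2, an inhibitor of plasminogen activators, fell by 2.33 ± 0.64 and ADAMTS1 by 0.94 ± 0.23. EDEM1, of protein quality control, fell there by 0.89 ± 0.16 and LDHA by 1.04 ± 0.26. FOSL1, an AP-1 subunit, fell by 2.93 ± 0.90 and DUSP5 by 1.11 ± 0.25 in that table. Gene totals of SERPINB2 and FOSL1 were on the lower side after every other siRNA too, without passing. A transcript of SQSTM1, an autophagy receptor, fell by 3.12 ± 0.35 in the authors' table, while the total of SQSTM1 was at -0.84 ± 0.34 (adjusted p = 0.255).

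**Figure D3:**
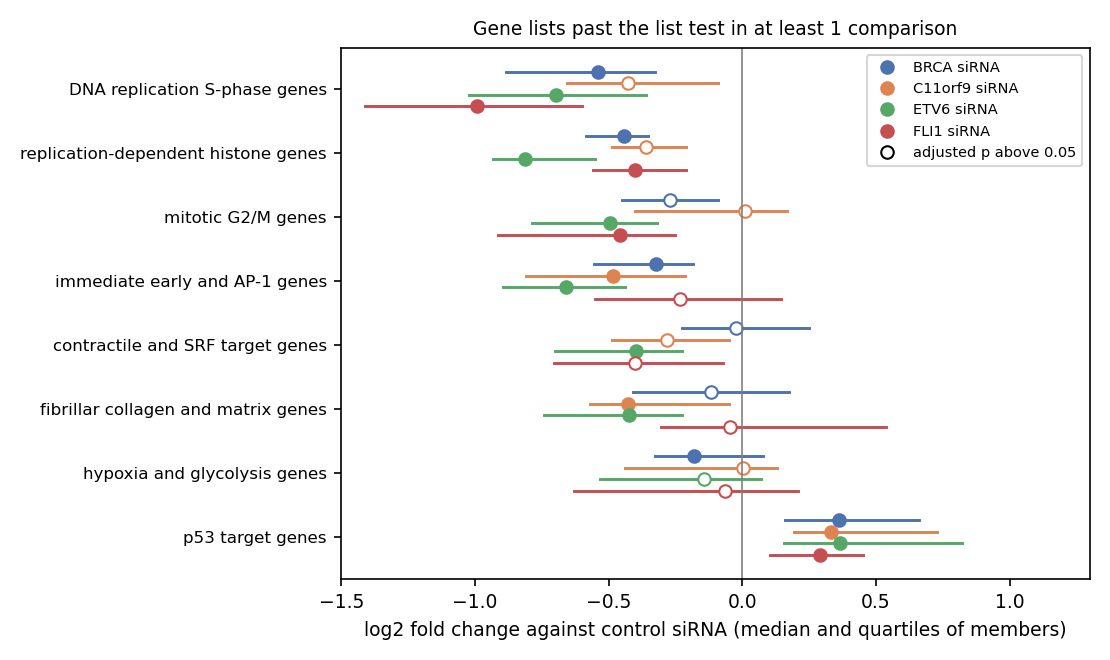
Median log2 fold change against control siRNA (point) and quartiles (line) of the members of 8 gene lists in the 4 knockdowns. Filled points passed the list test at an adjusted p under 0.05 with a preset correlation of 0.01, and open points did not. p53 target genes lie above 0 in all 4 knockdowns (medians 0.29 to 0.36), and DNA replication genes lie lowest after FLI1 siRNA (median -0.99).

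Of 26 gene lists, 25 had enough measured members to be tested, 8 passed in at least 1 knockdown with a preset correlation of 0.01, and only the p53 target genes passed in all 4. With a preset correlation of 0.05, 5 lists passed in at least 1 knockdown and 0 in all 4, as the p53 target genes did not pass after FLI1 siRNA (adjusted p = 0.280). The other 17 did not pass in any knockdown. Their smallest adjusted p was 0.0897 for interferon-stimulated genes, 0.0940 for TGF-beta and YAP targets, 0.0943 for cholesterol synthesis, 0.0996 for homologous recombination and Fanconi genes, 0.104 for autophagy and lysosome genes and 0.107 for cytosolic ribosomal proteins. It was 0.124 both for nuclear-encoded oxidative phosphorylation genes and for mitochondrially encoded transcripts, 0.127 for matrix metalloproteinases and plasminogen genes and 0.136 for ETS-family factors. It was 0.239 for ATF4 and unfolded protein response genes, 0.250 for NF-kB cytokines and 0.292 for RNA interference genes. Markers of other cell types were scarce. No leukocyte marker was measured (0), 3 to 4 epithelial markers (smallest adjusted p 0.229), 3 to 4 myelin genes (0.205) and 5 endothelial markers (0.157) were. Of the myelin genes MBP rose after ETV6 siRNA (adjusted p = 0.00239) and CLDN11 fell by 0.69 ± 0.21 after FLI1 siRNA in the authors' tables. The endothelial receptor TEK fell by 1.43 ± 0.36 after ETV6 siRNA in the authors' table, with its gene total at -0.52 ± 0.47 (adjusted p = 0.953). In 14 of 100 tests the median, the mean or the tested direction of a list differed in sign, and 0 of these tests passed. Some lower lists also kept their side in all 4 knockdowns. After BRCA, C11orf9, ETV6 and FLI1 siRNA the medians were -0.54, -0.43, -0.70 and -0.99 for DNA replication genes. They were -0.44, -0.36, -0.82 and -0.40 for histone genes, and -0.32, -0.48, -0.66 and -0.23 for immediate early genes. As the 3 control libraries are shared, a part of these falls may stem from them, which cannot be told apart here.

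The knockdowns were also compared with each other, as they share their control libraries. HDAC1 was lower after BRCA than after FLI1 siRNA (gene totals -1.35 against 0.13, adjusted p of the difference 1.43e-05), and CD44 was lower as well (-0.68 against -0.10, adjusted p = 3.96e-06). CDK6 was higher after BRCA siRNA than after C11orf9 siRNA (1.18 against -0.52, adjusted p = 5.87e-05) and than after ETV6 siRNA (-0.46, adjusted p = 2.90e-04). KIT was lower after FLI1 than after C11orf9 siRNA (-1.92 against 0.44, adjusted p = 2.89e-06), and STRA6 was higher after FLI1 than after ETV6 siRNA (1.21 against -2.88, adjusted p = 1.82e-04). ADAMTS5 was higher after ETV6 than after FLI1 siRNA (1.57 against -0.36, adjusted p = 0.0105). Over the 6 pairs 81 differences of gene totals passed, 1 of them between C11orf9 and ETV6, and a gene could count in several pairs. On simulated data this test found 1 to 9 of 50 genes that differed by 1 on the log2 scale. Of those that differed by 2 it found 15 to 24 of 50. Few differences therefore do not show that 2 siRNAs acted alike. For single transcripts the deposited errors gave 344 differences, and 1707 with the variance halved for the shared controls. DNA replication genes were lower after FLI1 than after BRCA siRNA (median difference 0.38, cameraPR adjusted p = 1.13e-04) and lower after ETV6 than after C11orf9 siRNA (0.31, adjusted p = 2.40e-04). Histone genes were lower after ETV6 than after C11orf9 siRNA (0.42, adjusted p = 8.08e-08). Collagen and matrix genes were lower after ETV6 than after FLI1 siRNA (median difference -0.32, adjusted p = 4.84e-04). Of these list differences only that of the histone genes held with a preset correlation of 0.05 (adjusted p = 0.00496). The other 3 were then at an adjusted p of 0.0530, 0.0629 and 0.0811 in the order given. For the p53 target genes no difference passed in any pair (smallest adjusted p 0.361). These tests of lists between knockdowns were added after the tables had been seen.

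TXNIP was higher in all 4 knockdowns in the authors' tables, by 0.96 after BRCA, 1.36 after C11orf9, 1.28 after ETV6 and 1.08 after FLI1 siRNA on the log2 scale. As a gene total it passed in 3, and was at 0.98 ± 0.27 (SE) after BRCA siRNA (Wald test, adjusted p = 0.0645). All 4 values are against the same control libraries, so they are not independent repeats. Altogether 6 transcripts passed in the same direction in all 4 tables, 39 in 3 and 153 in 2. Besides TXNIP these 6 were single transcripts of SOCS5, USP3 and KIRREL1, which were higher, and of NTM and ARPC4-TTLL3, which were lower. No gene total of SOCS5, USP3, KIRREL1 or NTM passed in any table (0 calls). The total of KIRREL1 was on the lower side in all 4 tables (-0.45, -0.72, -0.82 and -0.61 after BRCA, C11orf9, ETV6 and FLI1 siRNA) and that of USP3 after C11orf9 and ETV6 siRNA (-0.80 and -0.91), while that of NTM was at 0.18 after BRCA siRNA. Another transcript of KIRREL1 was lower in 3 tables. Of those in 3 tables, transcripts of TRIM2, OSBPL9, FUS and CREB3L2 lay next by the size of their change. Pairs of tables shared between 31 and 63 calls in the same direction, against 1.06 to 3.61 for independent tables. As the controls are shared, simulated knockdowns with no change at all shared a mean of 29.6 to 60.8 of their top-ranked transcripts, equal in number to the calls. Changes particular to 1 siRNA, which would lower this sharing, were not simulated. A pair that lies within its sets is therefore not shown to lack a common effect. The pair of C11orf9 and ETV6, with 60 shared calls, lay above the highest of its 20 simulated sets (45), and that of BRCA and ETV6, with 43, just above its highest (41), while the other 4 pairs did not. Across gene totals, which are not independent replicates, the log2 fold changes of C11orf9 and ETV6 siRNA had a Pearson correlation of 0.83, against 0.59 to 0.66 in the other pairs. Shared controls with no common effect gave a mean of 0.50 to 0.51 in simulated sets (at most 0.54), below all 6 pairs. Gene totals vary more in these sets than in the data, as their covariance (means 0.229 to 0.260) was above that observed (0.114 to 0.197).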

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

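No paired analysis was possible because the tables hold no values for single libraries, and for the same reason no library was left out and no other split of the libraries was tried. The gene totals and their rules for the spread were chosen after seeing the data. The 4 counts of changed transcripts (262 after BRCA, 233 after C11orf9, 313 after ETV6 and 623 after FLI1 siRNA) stayed within 1.5 times with a minimum change of 1.5-fold, without the filter on base means and after centring on the median. With a t distribution of 4 degrees of freedom the counts were 0, 0, 0 and 0 by that Wald test, with 514, 419, 572 and 924 transcripts at an unadjusted p under 0.05. Even the smallest unadjusted p of that test was 6.06e-05, after FLI1 siRNA, so it was too strict to tell stronger calls from weaker ones. It takes no account of the spread pooled across transcripts. Summed per gene, the counts were 45, 23, 40 and 285, and 62, 36, 55 and 330 with the first dispersion rule. A base mean of at least 50 left 128 after C11orf9 and 172 after ETV6 siRNA, and an adjusted p under 0.01 left 386 after FLI1 siRNA. Fewer transcripts were tested under that base mean. The cause of the other changes was not tested. Of the gene lists, 5, 3, 7 and 4 passed. With a preset correlation of 0.05 it was 3 after BRCA, 1 after C11orf9 and 4 after ETV6 siRNA, and with gene totals at that correlation 3 after BRCA and 1 after C11orf9 siRNA. With ranks 7 passed after C11orf9 and 9 after FLI1 siRNA. With gene totals 7 passed after C11orf9 siRNA, and against random lists 7 after C11orf9, 11 after ETV6 and 10 after FLI1 siRNA. The calls shared by pairs fell from 306 in all to 180 with a base mean of at least 50 and 50 by gene totals. The differences between knockdowns rose from 344 to 1707 with the variance halved for the shared controls, and were 81 by gene totals. Of the results of transcripts named by rule, 15 turned direction by the totals of their genes, none of these totals passing: PIP5K1A (-0.197) and KDM5C (-0.262) after BRCA siRNA, ERGIC2 (0.280) after C11orf9 siRNA, and FURIN (-0.282), NEK6 (0.134) and RPL8 (-0.234) after FLI1 siRNA. Of transcripts shared by several tables these were KIRREL1 (-0.449, -0.718, -0.821 and -0.610 after BRCA, C11orf9, ETV6 and FLI1 siRNA), USP3 (-0.804 after C11orf9 and -0.907 after ETV6 siRNA), NTM (0.179 after BRCA siRNA) and OSBPL9 (0.380 after BRCA and 0.605 after FLI1 siRNA). The share of changed genes that were higher went from 50.4% to 46.7% after BRCA and from 48.9% to 60.9% after C11orf9 siRNA. The list tests that passed kept their direction in these settings, while of those that did not pass 4 turned with gene totals, 4 with a base mean of at least 50 and 2 with ranks. Of single list results under these alternatives, 96 stayed past the threshold and 18 did not. Of results of single named transcripts 474 did and 256 did not, of these 153 under the t distribution and 88 by gene totals. Centring moved the log2 fold changes by at most 0.03.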

Other observations

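The tests of explanations and the genes named here were all chosen after the results had been seen. The total of ARRDC4, an arrestin of the family of TXNIP, rose by 1.01 ± 0.18 on the log2 scale (SE) after C11orf9 siRNA and by 0.61 ± 0.18 after FLI1 siRNA. After ETV6 siRNA it was at 1.01 ± 0.28, and after BRCA siRNA at 0.25 ± 0.23. The gene has 1 listed transcript, so the value after ETV6 siRNA is the deposited one. It passed by the authors' test (adjusted p = 0.0293) but not when corrected over gene totals (Wald test, adjusted p = 0.0861). ARRDC3 rose by 1.14 ± 0.23 after FLI1 siRNA and was at 0.71 ± 0.24, 0.61 ± 0.35 and 0.91 ± 0.39 after BRCA, C11orf9 and ETV6 siRNA, which did not pass. CYP2R1, an enzyme of vitamin D activation, rose after 3 siRNAs, by 2.22 ± 0.41 after C11orf9, 2.13 ± 0.47 after ETV6 and 1.51 ± 0.43 after FLI1 siRNA. After BRCA siRNA it was at 1.14 ± 0.55, which did not pass. Its mean normalised counts were low, from 15.6 after BRCA to 27.8 after C11orf9 siRNA. MLEC, a lectin of the endoplasmic reticulum, fell by 0.43 ± 0.10, 0.43 ± 0.11 and 1.08 ± 0.16 after C11orf9, ETV6 and FLI1 siRNA. After BRCA siRNA it was at -0.22 ± 0.09, which did not pass. ME1 fell by 0.73 ± 0.17 after ETV6 siRNA, beside its fall after C11orf9 siRNA, and was at 0.00 ± 0.11 after FLI1 siRNA. FAT3, a large cadherin, rose by 1.83 ± 0.39 after C11orf9 siRNA and passed after ETV6 siRNA as well (Wald test of gene totals, adjusted p = 9.96e-05). After BRCA siRNA it was at 1.39 ± 0.52, which did not pass, and its mean normalised counts were 17.9 to 26.6. All these changes are against the same control libraries, so repeats across siRNAs are not independent. TMEM158 differed in direction, lower after ETV6 siRNA (-1.15 ± 0.22) and higher after FLI1 siRNA (0.71 ± 0.20, adjusted p of the difference 1.03e-06).

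Most transcripts called with a log2 change of 3 or more belonged to genes whose total moved by less than 1.5-fold (75.2% of 741 such calls in genes with several listed transcripts). Whether the transcripts were exchanged in the cells or in the assignment of reads to transcripts was not tested, since reads were not analysed here. A state of the shared control libraries does not account for all of these calls, as the controls cancel between knockdowns: of 529 such transcripts tested, 125 (23.6%, 20.2% to 27.3%) differed between the knockdown they were called in and another, where false calls of that test could give 3.25%. For the other 404 it stays open, and 22.6% of 623 transcripts with an adjusted p in another table were called the same way there.

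p53 target genes were higher than other genes in all 4 knockdowns with a preset correlation of 0.01, and in 3 with one of 0.05, where FLI1 siRNA did not pass (adjusted p = 0.280). The size factors centre the typical transcript near 0, so the rise is relative to other genes, and whether it is one in absolute amount was not tested. A level that was low in the shared control libraries might give the same rise in every table. No difference of the list between knockdowns passed (smallest adjusted p 0.361 over 6 pairs), and this design cannot tell such a state of 3 control libraries from a response common to the 4 siRNAs, so the explanations cannot be told apart.

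The C11orf9 and ETV6 knockdowns had a higher correlation of gene totals than the other pairs. The shared control libraries alone would add the same covariance to every pair. For gene totals the covariance of this pair exceeded the highest of the other 5 pairs by 0.0206 (95% interval 0.00867 to 0.0311, from 2000 draws of genes), but for transcripts it was below that of ETV6 and FLI1 (0.631 against 0.655, difference -0.0238, -0.0928 to 0.0413). In simulated sets with shared controls and no common effect the Pearson correlation of gene totals of this pair was at most 0.53, against 0.83, and the Spearman correlation of transcripts at most 0.46, against 0.70, but gene totals vary more in these sets than in the data, and simulated sets give no firm bound. The interval for transcripts holds the whole interval for gene totals, so transcripts neither show nor exclude such an excess. With the excess seen for gene totals only, the share of the controls and a common effect cannot be told apart. A common effect of both siRNAs, including an off-target effect, and common handling of the libraries remain open. No batch is given in the labels, and MYRF was too low to be followed.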
